A study of Arabidopsis thaliana with 24 samples.

How the data were processed

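RNA sequencing measured transcript levels in rosettes of wild-type Arabidopsis thaliana grown from seed treated with water (not primed) or with methyl jasmonate (primed). Plants of each kind were sampled as uninfested controls, or 24 hours after infestation with the spider mite Tetranychus urticae or with caterpillars of the large white butterfly Pieris brassicae. This made 6 groups of 4 libraries, 24 in all. The labels number the biological replicates but do not say whether each was a separate plant or a pool, so the p-values measure the spread between these samples. RNA was extracted with a Qiagen RNeasy kit with an on-column DNase step, and libraries were made with a NEBNext Ultra RNA kit, per the labels.

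The deposited table gives raw counts per gene and library, in whole numbers. The deposited FPKM values, 1 set per library, were scaled by the authors per kilobase of gene length and by a library total that the tables do not give. In the 19481 genes with counts in every library, each FPKM value was checked to be the count times 1 constant per gene and 1 per library. The largest deviation was 3.73e-06 percent, and the library constants departed from the inverse of the library totals by up to 6.66%. Reads were aligned with HISAT2 to the TAIR10 genome per the submitters' processing notes. The version of the aligner, the counting tool, the annotation, the use of strand and any filters are not given in the sources used here. Reads shared between close paralogs (LHCB1.1 to LHCB1.3, PDF1.2a to PDF1.2c, AOC1 and AOC2, VSP1 and VSP2) therefore cannot be apportioned, and values of such genes may hold reads of their relatives. Gene symbols came from a RefSeq gene table of assembly TAIR10.1, which matched 32548 of 32833 identifiers (99.1%), and 0 of the listed loci had a conflicting symbol. Because that assembly carries another name than the build in the notes, no genome coordinates are printed.

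Library totals were between 15852109 and 27986799 counts, which limits the precision of weakly expressed genes. Of the 32833 genes, 6603 had no count in any library, and 20038 passed the filter on low counts (filterByExpr by group) and were tested. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, quasi-likelihood fit, 2-sided tests). All 24 libraries entered 1 fit with 6 group means and no replicate term. Changed genes had a Benjamini-Hochberg adjusted p under 0.05. The 12 contrasts were each pest against its control in not-primed and in primed plants, primed against not primed in each of the 3 infestation states, caterpillars against mites in each kind of plant, and 3 interactions. Fold changes are on the log2 scale with a standard error (SE) and n = 4 libraries per group. The SE was computed back from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. For genes near 0 counts it is only a rough guide. Levels are given in CPM, counts scaled to the normalized library size, with the SD. A fold against a group whose libraries are all at 0 is a lower bound computed from 3 counts over the group, and covers counting error only.

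Of the choices here, those made before the data were examined were the contrasts, the test, the 27 gene lists (413 loci, of which 388 were tested) and the rule for named genes. In each contrast with at least 20 changed genes, the rule took the 6 highest and 6 lowest log2 fold changes among changed genes with at least 5 CPM in a group and groups that did not overlap. It added the 3 members with the smallest adjusted p of each list called by camera, and 10 sentinel genes in every contrast (VSP2, LOX2, JAZ10, MYC2, PDF1.2a, PR1, CYP79F1, CYP79B2, PAD3 and LHCB1.3). With 1 to 19 changed genes it took the 10 with the smallest adjusted p, and with none the 5 with the smallest unadjusted p. Interactions did not need groups without overlap. A gene named in one contrast may be given in others.

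Each list was tested against all other tested genes with camera (limma 3.58.1; preset inter-gene correlation 0.01; 2-sided), with Benjamini-Hochberg adjustment over the lists within a contrast. Of the 324 list tests 108 passed, and 24 of these passed when the correlation was estimated from the data instead. Members past the threshold are counted over all tested genes, and beside this with p adjusted over the list alone. A list score per library is the mean log2 CPM (prior count 2) over the list's members, compared between groups with exact 2-sided permutation tests of 4 against 4 libraries, whose smallest possible p is 0.0286.

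On counts simulated for primed against not primed plants under mites, with 100 genes altered at each fold and 19834 genes tested, edgeR recovered 82% of the genes altered by a fold of 2 and 66% of those altered by a fold of 1.5, and called 6 unchanged genes. DESeq2 1.42.0 recovered 85% and 70% and called 21 unchanged genes. The limma test on FPKM recovered 83% and 65% of those among 18863 genes and called 9. In simulated counts for the same comparison under caterpillars with no gene altered, edgeR called 0 genes. A raised set of 20 genes gave a camera p of 4.19e-93, and an unaltered set 0.106.

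The alternatives tried were RLE size factors, no filter on low counts, an absolute log2 fold change of at least 1, the replicate number as a block, only the libraries of the groups compared, each library left out in turn, DESeq2, and limma on the log2 of the deposited FPKM. The limma fits used a pseudocount of 1 or 0.1 and a mean FPKM of at least 0.5, or a pseudocount of 1 and no filter. Leaving out not-primed control libraries 1 and 2, or 3 and 4, was added after seeing the data. No library and no column was left out of the comparisons.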

Results

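Transcripts were counted in 24 rosette libraries, 4 from each of 6 groups. Not-primed plants came from water-treated seed and primed plants from seed treated with methyl jasmonate, the methyl ester of the wound hormone jasmonic acid (JA). Each kind was sampled without pests, 24 hours after infestation with the spider mite Tetranychus urticae, or 24 hours after infestation with caterpillars of Pieris brassicae. The mite feeds on the content of single leaf cells and the caterpillar chews leaf tissue. Library totals were between 15852109 and 27986799 counts, and 20038 genes were tested. The series asks how seed treatment bears on defence and growth, and whether it alters the response to each pest. Values are log2 fold changes ± SE with n = 4 libraries per group unless another unit is named, and p-values are adjusted over all tested genes.

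The libraries separated first by infestation. The first principal component held 47.2% of the variance and the second 10.4%. Mean scores on the first were 60.5 in not-primed and 51.5 in primed controls, −49.4 and −50.6 under mites, and −7.4 and −4.6 under caterpillars. The 4 not-primed control libraries fell into a pair at 86.5 and 85.3 (replicates 1 and 2) and a pair at 34.8 and 35.6 (replicates 3 and 4), while the primed controls lay between 49.5 and 53.6. Replicates 3 and 4 had higher scores for JA output genes of the MYC branch (4.44 and 4.75, against 2.28 and 1.73 in replicates 1 and 2). They also had higher scores for the salicylic acid list (3.83 and 3.54, against 1.4 and 2.1) and the camalexin list (4.42 and 3.99, against −0.474 and 0.86). Contrasts that use these controls were therefore also run without either pair.

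**Figure D1:**
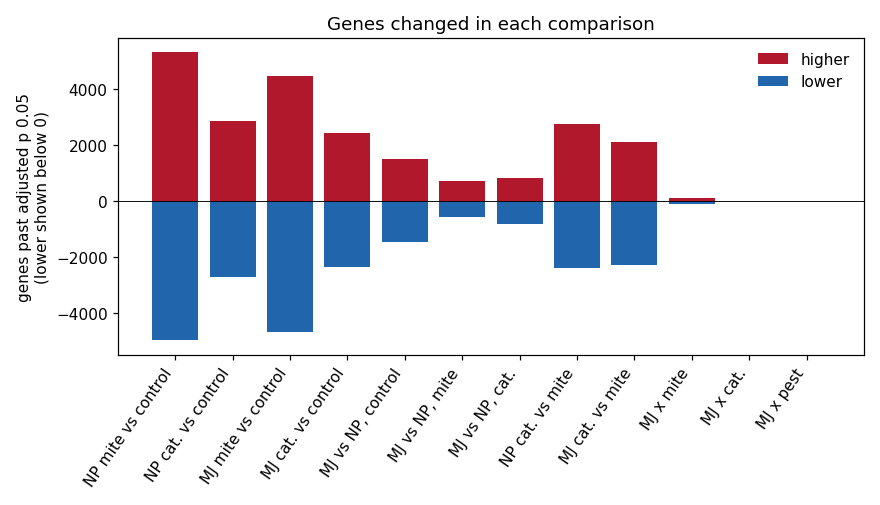
Number of genes (of 20038 tested) higher or lower at an adjusted p under 0.05 in each comparison, drawn as bars up and down from 0; NP is not primed, MJ is primed with methyl jasmonate, and cat. is caterpillar. Mites against control in not-primed plants gave 5310 higher and 4988 lower genes, and the interaction of priming with caterpillars gave 0.

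Mite feeding on not-primed plants raised the transcripts of JA synthesis and of JA-driven defence. VSP2, a vegetative storage protein gene and JA marker, went from 325 ± 279 CPM in controls to 3880 ± 426 CPM (SD, n = 4), a log2 fold change of 3.58 ± 0.51. The 13-lipoxygenase gene LOX2 rose by 3.55 ± 0.40 and the JA repressor gene JAZ10 by 4.18 ± 0.37. Among the genes that rose most were the calmodulin-like gene AT1G76640 (8.41 ± 0.60), the methyl salicylate and methyl benzoate synthase gene BSMT1 (8.15 ± 0.45), the terpene synthase genes TPS10 (AT2G24210, 7.97 ± 0.76) and TPS02 (7.36 ± 0.71), the plant defensin gene PDF1.2c (7.88 ± 1.06) and the triterpene gene LAS1 (7.24 ± 0.57). The genes that fell most were the wax gene CER4 (−3.43 ± 0.42), AT1G62510 (−3.17 ± 0.22), the BTB-TAZ gene BT2 (−2.98 ± 0.29), the cell wall gene XTH17 (−2.75 ± 0.37), the thionin gene THI2.2 (−2.75 ± 0.22) and AT3G24420 (−2.67 ± 0.28).

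By list, 15 of 17 JA synthesis genes rose under mites in not-primed plants, AOC1 (4.51 ± 0.32) and LOX3 (4.11 ± 0.30) among them, and 0 fell. Camera called 13 lists in this comparison, and each of these calls was lost with an estimated correlation (adjusted p between 0.0608 and 0.46). Of 20 JA signalling and repressor genes 19 rose and 1 fell, and all 10 JA catabolism genes rose. The MYC branch of JA output had 14 of 15 higher, including THI2.1 (4.93 ± 0.35) and CORI3 (4.83 ± 0.47). The branch driven by ERF factors with ethylene had 10 of 12 higher, or 12 adjusted over the list alone, with PDF1.2a up by 5.91 ± 0.78. Of 21 salicylic acid genes 17 rose (18 adjusted over the list alone), among them PR2 (4.11 ± 0.51) and EDS1 (0.97 ± 0.13). PR1 rose by 1.81 ± 0.56, but its call ended without mite replicate 1 (1.16, adjusted p = 0.0859) and without control replicates 1 and 2 (1.03, adjusted p = 0.108), and also in the fit on the groups compared alone (adjusted p = 0.0662). Pattern and damage response genes were higher in 16 of 18 cases, with MYB15 at 3.52 and RBOHD at 1.49. In indole glucosinolate synthesis 19 of 23 genes rose (20 adjusted over the list alone), with CYP79B2 at 2.21 ± 0.26, and in glucosinolate breakdown 9 of 11 rose (9 higher and 1 lower over the list alone), with MBP1 at 4.86. Sulfur genes were 8 higher and 1 lower of 9, with SDI1 at 3.21, and abscisic acid genes 11 higher and 1 lower of 16, with KIN1 at 5.21.

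Camera called the photosynthesis and phenylpropanoid lists lower under mites in not-primed plants. With an estimated correlation these calls were lost (adjusted p = 0.46 and 0.0608), and the phenylpropanoid score was 6.55 in either group (exact permutation p = 1). Of 25 photosynthesis genes 21 fell and 0 rose, with RBCS1B at −1.28, RBCS1A at −0.71 and LHCB1.3 at −0.27 ± 0.06, the last ending as a call by limma on unfiltered FPKM (adjusted p = 0.111). Of 17 phenylpropanoid and lignin genes 10 fell, such as CAD4 (−1.01) and PAL2 (−0.90), and 3 rose. Cell expansion genes were 13 lower and 3 higher of 22, which camera did not call (adjusted p = 0.0858). Aliphatic glucosinolate synthesis had 14 genes higher and 2 lower of 25 without a call (adjusted p = 0.12), with CYP79F1 at 0.70 ± 0.16, while its score was 6.56 against 6.18 in controls without overlap (exact permutation p = 0.0286, the smallest possible, and 0.0429 adjusted over the lists). Heat shock genes were 1 higher and 4 lower of 6 without a camera call (adjusted p = 0.123), while their score was lower by −0.55 with the same exact permutation p. The camalexin gene PAD3 did not pass (0.76 ± 0.61, adjusted p = 0.32), but it did without control replicates 3 and 4 (4.54, adjusted p = 1.03e-05) and by limma with a pseudocount of 0.1 (2.08, adjusted p = 0.0402).

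In this comparison 10298 genes changed, 5310 higher and 4988 lower, of which 1607 and 464 changed at least by a fold of 2. In 45.8% of tested genes the 4 libraries of one group lay all above or all below the other, against 2.86% by chance. Camera gave adjusted p from 5.87e-13 for JA synthesis to 0.00142 for phenylpropanoids.

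**Figure D2:**
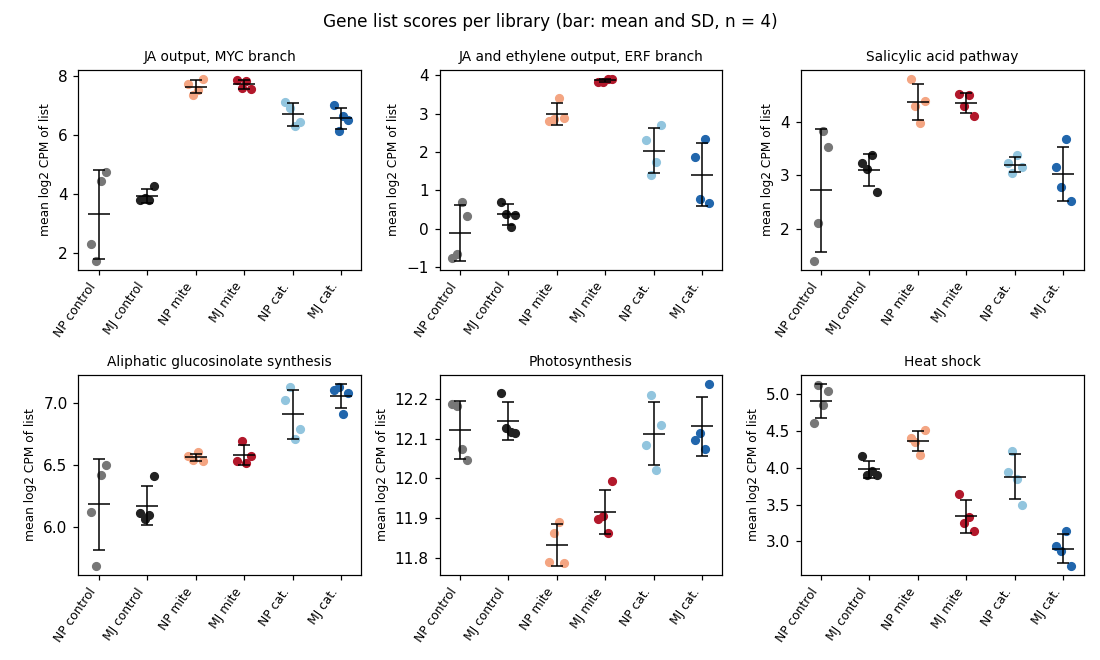
Scores per library (mean log2 CPM over the members) of 6 gene lists in the 6 groups, as points with the mean and SD (n = 4); NP is not primed, MJ primed, and cat. caterpillar. The MYC branch score was 3.30 ± 1.52 in not-primed controls and 7.63 ± 0.23 under mites, and the heat shock score was lower in primed than in not-primed plants in each infestation state.

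Caterpillar feeding on not-primed plants raised the JA genes too, together with glucosinolate and flavonoid genes, and no call was made for the salicylic acid or photosynthesis lists. The salicylic acid result depends on the pair of controls used, as given below. VSP2 rose by 3.48 ± 0.51, LOX2 by 3.06 and JAZ10 by 3.08. The genes that rose most were ILL5, a relative of amidohydrolase genes (at least 618-fold, from 0 counts in controls), AT4G10290 (at least 261-fold, from 0 counts), TPS10 (AT2G24210, 9.06), BSMT1 (7.46), AT2G30830 (7.21) and the JA-isoleucine hydroxylase gene CYP94B3 (6.88). The lowest were CER4 (−2.70), AT1G62510 (−2.07), the small heat shock gene HSP17.6II (−1.80), XTH17 (−1.79), EGY3 (−1.70) and BT5 (−1.67). The sentinel genes PR1 (−0.16 ± 0.59, adjusted p = 0.88), PAD3 (0.42, adjusted p = 0.67) and LHCB1.3 (0.07 ± 0.06, adjusted p = 0.45) did not pass, but PAD3 did without control replicates 3 and 4 (4.18, adjusted p = 8.13e-05).

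All 17 JA synthesis genes and all 10 JA catabolism genes rose under caterpillars in not-primed plants, with LOX3 at 4.01 and JMT at 2.33. JA signalling genes were 16 of 20 higher (17 adjusted over the list alone) and MYC-branch genes 13 of 15 (14 over the list alone), with CORI3 at 4.67. Of 25 aliphatic glucosinolate genes 21 rose and 2 fell, with the regulator MYB76 at 1.96 and CYP79F1 at 0.94. Of 23 indole glucosinolate genes 20 rose, with MYB34 at 1.5 and GGP1 at 1.54, and the list alone gave 20 higher and 1 lower. Glucosinolate breakdown had 9 of 11 higher (ESP at 1.13) and sulfur genes 7 of 9 (SDI1 at 2.84). Flavonoid and anthocyanin genes were 16 higher and 2 lower of 20, with UGT79B1 at 2.67 and 5MAT at 2.32. Abscisic acid genes were 10 higher and 1 lower of 16, with KIN1 at 5.20. Heat shock genes were 4 lower of 6, with HSP70 at −1.54 and HSP90-1 at −1.10, and phenylpropanoid genes were 4 higher and 6 lower of 17 (4 and 9 over the list alone), with HCT at −0.43. The phenylpropanoid score was 6.56 against 6.55 in controls, with overlap (exact permutation p = 0.686). With an estimated correlation 11 of these 12 lists kept their call, and the aliphatic list lost it (adjusted p = 0.106).

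Calls of the same comparison that were lost with an estimated correlation were the ERF branch with 6 of 12 higher (8 over the list alone; PDF1.2a at 5.08 ± 0.80), pattern and damage genes with 11 of 18 higher, and cell expansion with 2 higher and 11 lower of 22 (2 and 12 over the list alone; EXPA8 at −0.97). Senescence genes were 4 of 9 higher and guard cell, phloem and trichome markers 6 of 12 higher. The 1 tested root marker, PYK10, which rosettes also express, rose by 1.02. Their adjusted p with an estimated correlation was 0.145 for the ERF, pattern and marker lists, 0.154 for cell expansion, 0.35 for senescence and 0.0692 for PYK10. The salicylic acid list had 1 gene higher of 21 (camera adjusted p = 0.142) and photosynthesis 3 higher and 4 lower of 25 (adjusted p = 0.839). The mean salicylic acid score under caterpillars was 3.2, above control replicates 1 and 2 (1.4 and 2.1) and below 3 and 4 (3.83 and 3.54). Its lack of a call thus averages over pairs that point opposite ways. In all 5574 genes changed, 2839 higher and 2735 lower, and 25% of genes had groups without overlap against 2.86% by chance. Without control replicates 1 and 2 the count was 2485.

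Mites raised JA, salicylic acid, defensin and indole glucosinolate genes in primed plants. Camera called 18 lists, and with an estimated correlation each call was lost (adjusted p between 0.102 and 0.603). Most raised were AT2G41800 (at least 215-fold, from 0 counts in controls), AT1G76640 (10.29), BSMT1 (8.98), AT3G49340 (8.80) and the defensin genes PDF1.3 (8.57) and PDF1.2a (8.36 ± 0.91). The sugar transporter gene SAG29 (−3.70), EGY3 (−3.44), AT1G62510 (−3.34) and CER4 (−3.27) fell most. VSP2 rose by 3.31, LOX2 by 3.57, JAZ10 by 4.95 and PR1 by 2.68 ± 0.58. JA synthesis genes were 15 of 17 higher, signalling genes 16 of 20 (16 higher and 2 lower over the list alone), catabolism genes 10 of 10 and MYC-branch genes 14 of 15, with NATA1 at 6.84 and CLH1 at 3.26. The ERF branch had 11 of 12 higher, salicylic acid genes 16 of 21 (18 over the list alone; EDS5 at 2.17), pattern genes 17 of 18, indole glucosinolate genes 21 of 23 (22 over the list alone) and breakdown genes 8 of 11. Aliphatic glucosinolate genes were 14 higher and 2 lower of 25 (15 and 2 over the list alone), with BCAT4 at 1.06 and the regulator MYB28 at −1.01. Flavonoid genes were 13 higher and 2 lower of 20 (13 and 3 over the list alone), with MYB113 at 4.84 and CHIL at −1.13. Sulfur genes were 8 higher and 1 lower of 9, and abscisic acid genes 11 higher and 2 lower of 16.

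Lists that camera called lower in primed plants under mites, each lost with an estimated correlation (adjusted p between 0.102 and 0.502), were photosynthesis (0 higher, 16 lower of 25, or 17 lower over the list alone), phenylpropanoids (4 higher, 10 lower of 17, with a score of 6.53 in either group, exact permutation p = 0.857), cell expansion (3 higher and 14 lower of 22, or 3 and 15 over the list alone; EXPA11 at −1.69) and heat shock (4 lower of 6, HSP70 at −1.63). PYK10 rose by 1.32. The comparison had 9166 changed genes, 4463 higher and 4703 lower, with 43.4% of genes without overlap against 2.86% by chance.

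Caterpillars on primed plants raised ILL5 (at least 588-fold, from 0 counts in controls), AT4G10290 (9.04), AT1G76640 (8.27), TPS10 (AT2G24210, 8.16) and BSMT1 (7.81). CER4 (−2.68), AT1G62510 (−2.41), EGY3 (−2.32), SAG29 (−2.09), AT3G62070 (−2.02) and DREB26 (−1.87) fell most. JA synthesis genes were 15 of 17 higher (16 over the list alone; LOX3 at 3.88), signalling genes 15 higher and 1 lower of 20 (16 and 1 over the list alone; JAZ5 at 3.08), catabolism genes 10 of 10 (CYP94B3 at 6.22) and MYC-branch genes 13 of 15 (CORI3 at 4.53). Aliphatic glucosinolate genes were 22 of 25 higher (22 higher and 1 lower over the list alone; BCAT4 at 1.69, GSTU20 at 1.37 and CYP79F1 at 1.24), and indole genes 20 higher and 1 lower of 23, with CYP81F4 at 3.10. Breakdown genes were 8 of 11 higher (9 over the list alone), sulfur genes 8 of 9, and flavonoid genes 16 of 20, with TT19 at 2.99, 5MAT at 2.96 and the chalcone synthase gene CHS at 1.19. Heat shock genes were 4 of 6 lower, with HSP70 at −1.69, and PYK10 rose by 1.41.

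Those calls were kept with an estimated correlation, though PYK10 as a list of 1 tested gene has none to estimate. In primed plants under caterpillars 4 others were lost. They were the ERF branch (3 of 12 higher, 6 over the list alone; adjusted p = 0.489 with an estimated correlation), pattern genes (10 of 18 higher, or 11 higher and 1 lower over the list alone; adjusted p = 0.259), cell expansion (2 higher and 11 lower of 22, or 2 and 13 over the list alone; adjusted p = 0.064) and abscisic acid (8 higher and 2 lower of 16, or 9 and 2 over the list alone; adjusted p = 0.246). VSP2 rose by 3.58, LOX2 by 3.05 and PDF1.2a by 4.51 ± 1.17, while PR1 did not pass (0.41, adjusted p = 0.69). The salicylic acid list had 2 genes higher of 21 (1 over the list alone) and no call (adjusted p = 0.95). In all 4789 genes changed, 2429 higher and 2360 lower, with 25.3% of genes without overlap against 2.86% by chance.

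**Figure D3:**
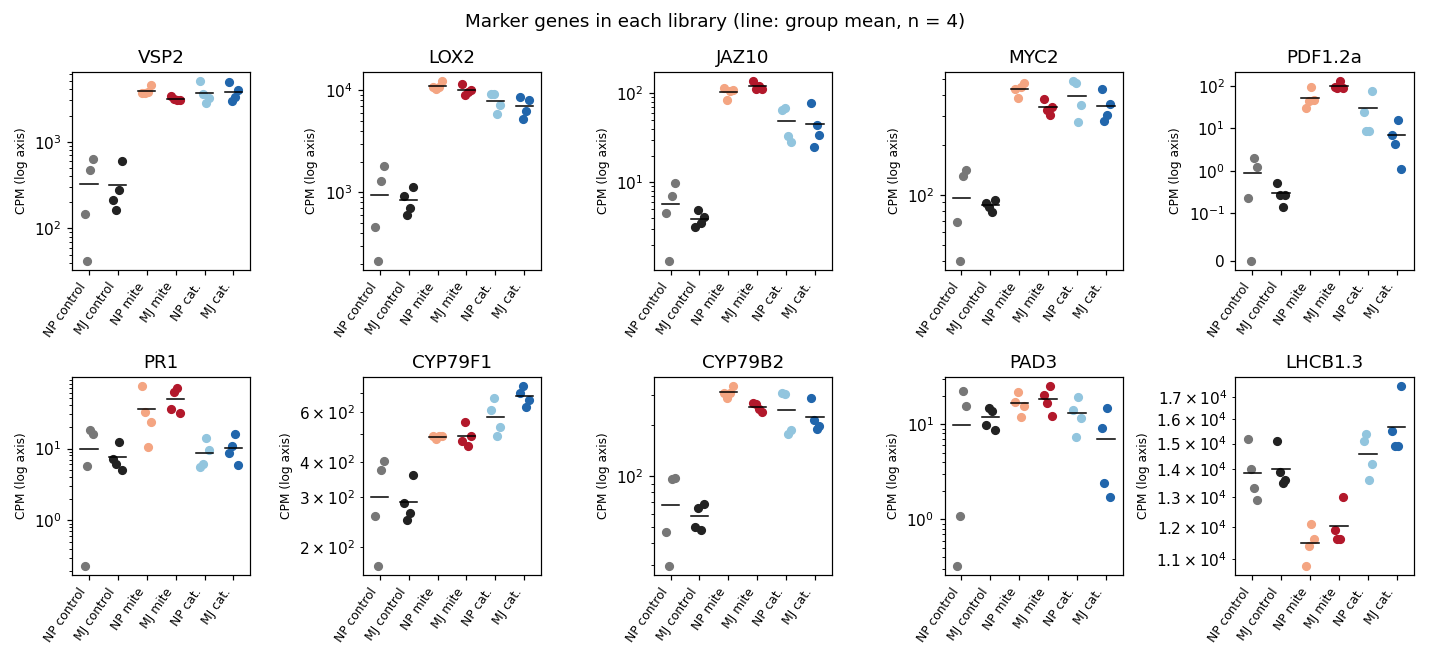
Levels of the 10 sentinel genes in CPM on a log axis (for PDF1.2a linear below 0.1), each point a library and each line a group mean (n = 4); NP is not primed, MJ primed, and cat. caterpillar. VSP2 was at 325 ± 279 CPM in not-primed controls, 3880 ± 426 under mites and 3630 ± 980 under caterpillars, and PR1 at 9.97 ± 8.48, 35.0 ± 27.4 and 8.72.

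The responses to the pests overlapped within each kind of plant. In not-primed plants 2493 genes rose and 2482 fell under both pests, against 752 and 681 by chance, and 29 went opposite ways. The correlation of the log2 fold changes across genes, which are not independent replicates, was r = 0.818, with a covariance of 0.411. Both contrasts share their controls, and simulated unchanged groups against shared controls gave r of 0.501 with a covariance of 0.021 and 0 genes called in both. The simulation drew libraries independently, with the same spread per gene in each group, so it left out the pairs among the not-primed controls. With the control libraries split between the pests r was between 0.528 and 0.749. In primed plants 1940 genes rose and 2022 fell under both, against 541 and 554 by chance, and 34 went opposite ways. There r was 0.763, the simulated value 0.503, and the split controls gave 0.637 to 0.691.

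Set directly against mites, caterpillars left salicylic acid genes lower and photosynthesis and aliphatic glucosinolate genes higher in not-primed plants. Camera called 11 lists in this contrast, and each call was lost with an estimated correlation (adjusted p between 0.235 and 0.792). Of 21 salicylic acid genes 17 were lower, among them PR2 (−3.26) and PBS3 (−2.01), and of 25 photosynthesis genes 23 were higher (24 over the list alone), with LHCB2.3 at 0.68 and RBCS1A at 0.47. LHCB1.3 was higher by 0.34, a call that ended by limma on unfiltered FPKM (adjusted p = 0.0846). PR1 was lower by −1.97, but its call ended without mite replicate 1 (−1.33, adjusted p = 0.0907) and by limma (0.0551, 0.126 and 0.0873 in its 3 fits). Aliphatic glucosinolate genes were 16 higher and 1 lower of 25, with IPMI2 at 0.84 and MYB28 at 0.63. Flavonoid genes were 8 higher of 20 (10 higher and 1 lower over the list alone; CHIL at 1.06 and FLS1 at 0.96), and phenylpropanoid genes 8 higher and 2 lower of 17 (8 and 3 over the list alone; 4CL3 at 1.01). The phenylpropanoid score was 6.56 against 6.55 under mites, with overlap (exact permutation p = 0.771). JA signalling genes were 4 of 20 lower (JAZ10 at −1.10), MYC-branch genes 6 of 15 (8 over the list alone; THI2.1 at −3.12) and ERF-branch genes 3 of 12 (4 over the list alone; ERF2 at −1.29). Pattern genes were 6 of 18 lower (1 higher and 9 lower over the list alone; MPK3 at −0.57), indole genes 3 of 23 (2 over the list alone; IGMT1 at −0.85) and heat shock genes 2 of 6 (HSFA2 at −1.10).

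The genes highest in caterpillar-fed over mite-fed not-primed plants were ILL5 (2.87), the phosphoinositide phosphatase gene 5PTASE11 (2.39), OEP6 (2.16 ± 0.09), AT3G22620 (2.04), AT2G30830 (1.88) and AT1G26790 (1.76). The lowest were AT3G49340 (−6.90), BGLU22 (−3.64), the receptor-like kinase gene CRK13 (−3.55), EARLI1 (−3.47), AT5G24200 (−3.38) and AT1G54020 (−3.36). In all 5147 genes differed, 2753 higher and 2394 lower under caterpillars, and 596 of the lower against 116 of the higher differed at least by a fold of 2. In 26.3% of genes the groups did not overlap, against 2.86% by chance. Camera gave adjusted p from 2.59e-09 for photosynthesis to 0.0381 for JA signalling.

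In primed plants the same contrast of the pests had the plant defensin genes among its lowest. PDF1.2b (−4.48), PDF1.2c (−4.46), PDF1.2a (−3.84), AACT1 (−4.40), EARLI1 (−4.40), AT4G16260 (−4.29) and AT3G49340 (−7.53) were lower under caterpillars than under mites, and PELPK1 (4.28), ILL5 (3.40), AT3G22620 (2.91) and 5PTASE11 (2.56) were higher. Camera called 10 lists, and each call was lost with an estimated correlation (adjusted p between 0.121 and 0.623). ERF-branch genes were 9 of 12 lower (11 over the list alone; PR4 at −2.04), salicylic acid genes 15 of 21 (17 over the list alone; PR2 at −3.25 and EDS1 at −1.10) and pattern genes 13 of 18 (14 over the list alone; MYB15 at −2.10). JA signalling genes were 1 higher and 8 lower of 20 (1 and 9 over the list alone), MYC-branch genes 5 of 15 lower (8 over the list alone; THI2.1 at −3.43) and indole genes 7 of 23 lower. Aliphatic glucosinolate genes were 18 of 25 higher (19 higher and 1 lower over the list alone), with MYB28 at 0.84 and FMOGS-OX3 at 0.90. Flavonoid genes were 13 of 20 higher (16 over the list alone; CHIL at 1.22), photosynthesis genes 13 of 25 (21 over the list alone; LHCB2.3 at 0.69) and phenylpropanoid genes 7 higher and 3 lower of 17 (9 and 3 over the list alone). The phenylpropanoid score was 6.56 against 6.53 under mites, with overlap (exact permutation p = 0.429). PR1 was at −2.27 (adjusted p = 0.0044, and 0.0533 by limma with a pseudocount of 0.1). In all 4404 genes differed, 2104 higher and 2300 lower, with 23.4% without overlap against 2.86% by chance. Camera gave adjusted p from 2.21e-11 for salicylic acid to 0.0205 for JA signalling.

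Priming without pests raised BT2 most, lowered the heat shock genes and moved no sentinel gene past the threshold. BT2 went from 15.3 ± 4.41 CPM in not-primed to 170 ± 17.2 CPM in primed controls (SD, n = 4), a log2 fold change of 3.47 ± 0.21. AT3G15450 (2.50), SIS (2.42), AT1G80440 (2.27), AT2G44130 (2.26) and the dark-induced gene SEN1 (2.25) were also among the highest. The lowest included CP1 (−1.40), the cytokinin response regulator gene ARR6 (−1.21), BBX31 (−1.18) and MES18 (−1.19), whose call ended without control replicates 1 and 2 (−0.65, adjusted p = 0.195). All 6 tested heat shock genes fell, with HSP70 at −0.82, HSP101 at −0.86 and HSP17.4 at −1.01. Camera called the heat shock list and 4 others, and each call was lost with an estimated correlation (adjusted p = 0.062 for heat shock and 0.516 for the others). Senescence genes were 4 of 9 higher (5 higher and 1 lower over the list alone; NAP at 1.81), abscisic acid genes 4 of 16 higher (7 over the list alone; ABF3 at 0.50), sulfur genes 4 higher and 1 lower of 9 (6 and 2 over the list alone; SHM7 at 0.80) and flavonoid genes 5 of 20 lower (FLS1 at −0.52 and CHS at −0.45). Without control replicates 1 and 2 some members of these lists lost their calls. They were the abscisic acid genes RAB18 (0.48, adjusted p = 0.162) and RD26 (0.70, 0.226), the senescence gene ORE1 (0.94, 0.127) and the sulfur gene LSU1 (0.92, 0.177). The flavonoid score was 2.89 in primed and 3.15 in not-primed controls, with overlap (exact permutation p = 0.514). Not-primed replicates 3 and 4 (3.614 and 3.79) lay above all primed controls (2.732 to 3.203), and replicates 1 and 2 (3 and 2.202) did not. The lower flavonoid direction thus depended on replicates 3 and 4. JA synthesis genes were 2 of 17 higher without a call (adjusted p = 0.464). The sentinels that did not pass included VSP2 (−0.05 ± 0.46), LOX2 (−0.16), JAZ10 (−0.55) and PDF1.2a (−1.53 ± 1.74).

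This contrast of controls had 2962 changed genes, 1490 higher and 1472 lower, of which 169 and 58 changed at least by a fold of 2, and 18% without overlap against 2.86% by chance. The share of changed genes that were higher depended on the scaling, at 50.3% here, 41.9% with RLE size factors, 41.8% by DESeq2 and 42.7% by limma on FPKM. The count was 1370 without control replicates 1 and 2, 4537 without replicates 3 and 4, and 1854 without replicate 1. The sign of several sentinels turned with the pair left out. Without replicates 1 and 2, LOX2 (−0.88), MYC2 (−0.66), CYP79F1 (−0.42) and CYP79B2 (−0.74) were called lower in primed plants, and without replicates 3 and 4, VSP2 (1.71), LOX2 (1.28), MYC2 (0.63), CYP79F1 (0.40) and PAD3 (4.02) were called higher. Camera called the 5 lists named, at adjusted p of 7.15e-08 for heat shock, 0.00142 for senescence, 0.00209 for flavonoids, 0.0034 for abscisic acid and 0.0122 for sulfur.

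Under mites, primed plants again had more BT2 (45.1 ± 7.94 against 1.98 ± 0.948 CPM, SD, n = 4), with a log2 fold change of 4.55 ± 0.27. AT2G20670 (3.11), AT3G15450 (3.08), the NAC factor gene ANAC055 (3.03), AT1G80440 (2.98) and BT5 (2.97) were higher. BBX31 (−1.91), BBX30 (−1.72), AT2G27420 (−1.68), HSFA2 (−1.64), BBX29 (−1.60) and AT4G27657 (−1.50) were lower. Of 6 heat shock genes 5 fell (6 over the list alone), with HSP70 at −1.08 and HSP101 at −0.86. ERF-branch genes were 3 of 12 higher (6 over the list alone), with the regulator ORA59 at 1.44. The others of the 3, ERF5 (0.84) and ERF104 (0.93), both lost their calls without not-primed mite replicate 2 (adjusted p = 0.156 and 0.0977) or 4 (0.138 and 0.059) or primed mite replicate 4 (0.154 and 0.0915), and by limma on unfiltered FPKM (0.0769 and 0.0526). ERF5 also lost it with a replicate block (0.0648), without the count filter (0.0528), by limma with a pseudocount of 0.1 (0.0663) and without not-primed mite replicate 1 (0.0733) or primed mite replicate 2 (0.141), and ERF104 without primed mite replicate 3 (0.0551). PDF1.2a did not pass (0.91 ± 0.49, adjusted p = 0.36), though in a fit on the groups compared alone it did (adjusted p = 0.0118), as did VSP2 (−0.31, 0.00497), MYC2 (−0.37, 0.00162) and CYP79B2 (−0.28, 0.00412), lower in primed plants. The main fit takes 1 spread per gene from all 24 libraries, the not-primed controls with their pairs included. Under mites VSP2 was at 3620 to 4510 CPM in not-primed and 3010 to 3350 CPM in primed libraries. Whether the spread of the controls kept these genes from passing was not tested. In all 1275 genes changed, 709 higher and 566 lower, with 12.1% without overlap against 2.86% by chance. The heat shock call (camera adjusted p = 6.06e-13) held with an estimated correlation (adjusted p = 0.00646), and the ERF call (adjusted p = 0.00396) was lost (0.974).

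Under caterpillars, primed plants had 1634 changed genes, 800 higher and 834 lower. BT2 was higher by 3.26 ± 0.23, followed by AT3G15450 (2.83), AT1G80440 (2.69), AT5G64190 (2.52), AT2G20670 (2.40) and AT5G19120 (2.22). AT4G27657 (−1.44), AT2G27420 (−1.32), AT3G44450 (−1.21) and CP1 (−1.21) were lower. All 6 heat shock genes fell, with HSP70 at −0.98 and HSP17.4 at −1.16, the latter ending as a call without primed caterpillar replicate 4 (−1.01, adjusted p = 0.0531). PDF1.2a was lower by −2.09 ± 0.59 (adjusted p = 0.028), but the call ended with all libraries kept by DESeq2 (adjusted p = 0.0995), in the fit on the groups compared alone (0.107) and by limma (0.0611, 0.164 and 0.0985 in its 3 fits). Without not-primed caterpillar replicate 4 it was −1.0 (adjusted p = 0.299), and the call also ended without primed caterpillar replicate 1 (adjusted p = 0.0595), 2 (0.0672) or 4 (0.0996). The ERF branch had 3 of 12 lower (2 higher and 4 lower over the list alone) and no call (adjusted p = 0.793). Heat shock was the 1 list called (camera adjusted p = 3.25e-10, and 0.0236 with an estimated correlation). In 12.8% of genes the groups did not overlap, against 2.86% by chance, and the count of changed genes was 1032 without primed caterpillar replicate 4.

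**Figure D4:**
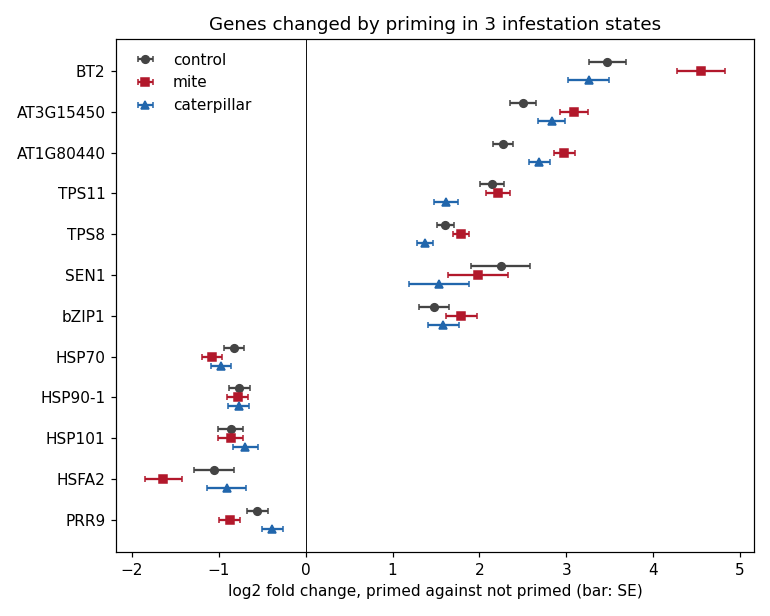
Log2 fold change ± SE (n = 4 per group) of primed against not-primed plants for 12 genes in the 3 infestation states, with cat. for caterpillar. BT2 was higher by 3.47, 4.55 and 3.26 in controls, under mites and under caterpillars, and HSP70 was lower at −0.82, −1.08 and −0.98.

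Across the 3 infestation states 349 genes were higher and 203 lower in primed plants in every state, 552 in all, against 2.1 and 1.73 by chance. Higher in each were TPS8 (1.61, 1.79 and 1.37 in controls, under mites and under caterpillars) and TPS11 (2.14, 2.22 and 1.62), which encode relatives of trehalose-phosphate synthase, the bZIP factor gene bZIP1 (1.48, 1.79 and 1.58) and SEN1 (2.25, 1.98 and 1.53). Lower in each were the B-box genes BBX31 (−1.18, −1.91 and −1.12) and BBX29 (−0.85, −1.60 and −0.77), HSP90-1 (−0.77, −0.78 and −0.77) and the clock gene PRR9 (−0.56, −0.88 and −0.39). Heat shock scores of primed and not-primed libraries were 3.98 ± 0.12 and 4.91 ± 0.23 in controls, 3.34 ± 0.22 and 4.36 ± 0.14 under mites, and 2.90 ± 0.19 and 3.88 ± 0.31 under caterpillars (SD, n = 4). They did not overlap in any state, with an exact permutation p of 0.0286, the smallest possible, which after adjustment over the lists was 0.193, 0.257 and 0.644. Of 3951 genes called for priming in any state, 1368 were called in 2 or more, and 16 of these in opposite directions. Across genes the priming fold changes had r = 0.347 between controls and mites, 0.411 between controls and caterpillars, and 0.341 between the pests.

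Whether priming altered the mite response was tested as an interaction, which called 221 genes, 106 higher and 115 lower. The abscisic acid receptor gene PYL5 had an interaction of 1.60 ± 0.23, at −1.07 under mites in not-primed and 0.53 in primed plants. BT5 (1.57 ± 0.19), AT1G06830 (1.5 ± 0.30), AT5G61590 (1.24), AT5G21940 (1.21) and AT2G20670 (1.15) also had a higher response in primed plants. Lower were the galactinol synthase gene GolS2 (−1.84 ± 0.45), the proline synthesis gene P5CS1 (−1.40 ± 0.26, at 1.28 in not-primed and −0.12 in primed plants), BT1 (−1.32 ± 0.15), the abscisic acid-related factor genes HB-12 (−1.08) and ABF3 (−0.76), EGY3 (−1.08) and the floral integrator SOC1 (−0.56). GolS2 lost its call in each fit without 1 library (adjusted p up to 0.0958), except those without not-primed control replicate 3 or 4 or primed mite replicate 1. SOC1 lost it without not-primed control replicate 1 or 2, primed control replicate 1, 2 or 4, not-primed mite replicate 1 or 4, or primed mite replicate 2 or 4 (up to 0.0825). EGY3 lost it without primed control replicate 2, not-primed mite replicate 1 or primed mite replicate 3 or 4 (up to 0.065). Without not-primed control replicates 1 and 2 together, AT1G06830 (1.08, adjusted p = 0.0929), GolS2 (−1.61, 0.15) and SOC1 (−0.56, 0.0762) lost their calls. By limma on unfiltered FPKM so did GolS2 (0.081), EGY3 (0.0542) and SOC1 (0.0601), and GolS2 in the other 2 limma fits as well (0.0527 and 0.0644). Camera called lower interactions for abscisic acid genes (1 of 16 lower, 6 over the list alone; adjusted p = 2.96e-05), sulfur genes (0 of 9, or 1 higher and 2 lower over the list alone; 0.0393) and flower markers (1 of 11 lower, SOC1; 0.0393), and each was lost with an estimated correlation (adjusted p = 0.922). The sulfur interaction depends on the pair of not-primed controls used. Its score was 3.21 and 3.17 in replicates 1 and 2, 3.77 and 3.84 in 3 and 4, and 3.94 in primed controls. Under mites it was 5.11 in not-primed and 5.23 in primed plants. None of the sentinel genes passed, but without not-primed control replicates 3 and 4 VSP2 (−2.02), LOX2 (−1.41), MYC2 (−1.0), CYP79B2 (−0.85) and PAD3 (−3.87) were called lower.

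That count of 221 depended on single libraries and on the tool. It was 80, 121, 607 and 611 without not-primed control replicates 1 to 4, and 93, 80 and 103 without primed control replicates 1, 2 and 4. Without not-primed mite replicates 1, 2 and 4 it was 110, 125 and 116, and without primed mite replicates 2 to 4 it was 90, 85 and 79. It was 111 without not-primed control replicates 1 and 2, 2069 without 3 and 4, and 691 by DESeq2. The share of called genes that were higher was 48% here, 64.3% with RLE size factors, 68.9% by DESeq2 and 62.4% by limma on FPKM.

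For caterpillars the interaction called 0 genes with edgeR, while 1445 had an unadjusted p under 0.05. DESeq2 called 10 and limma on filtered FPKM 0. The 5 smallest unadjusted p belonged to BT1 (−0.86), the lipid transfer gene AZI1 (2.78 ± 0.50), UPL5 (−0.41), AT2G29670 (−0.70) and TPPE (−0.73), which failed the correction, with adjusted p of 0.0921 for BT1 and AZI1. BT1 passed without the count filter (adjusted p = 0.0353) and without not-primed control replicate 2 (0.00959), AZI1 without primed caterpillar replicate 4 (0.0246) and TPPE without primed caterpillar replicate 2 (0.0393), and by DESeq2 the adjusted p was 0.000235 for BT1 and AZI1, 0.0158 for AT2G29670 and 0.0269 for TPPE. Without not-primed control replicates 1 and 2 there were 9 calls, and 486 without 3 and 4, the sentinels LOX2 (−1.44) and PAD3 (−4.91) among them. Camera called 9 lists with no member past the threshold, and each call was lost with an estimated correlation (adjusted p between 0.32 and 0.73). Higher in the primed response were flavonoid genes (median 0.47, 2 of 20 higher over the list alone) and aliphatic glucosinolate genes (0.21). By list score, both directions turn with the pair of not-primed controls used. The flavonoid score was 3 and 2.202 in replicates 1 and 2, 3.614 and 3.79 in 3 and 4, and 2.89 in primed controls. Under caterpillars it was 4.74 in not-primed and 4.78 in primed plants. The aliphatic score was 6.119 and 5.682 against 6.42 and 6.501, with 6.17 in primed controls. Under caterpillars it was 6.91 and 7.06. Lower medians were those of camalexin (−0.76), abscisic acid (−0.52, 1 of 16 lower over the list alone), the ERF branch (−0.52), senescence (−0.43), guard cell, phloem and trichome markers (−0.17, 1 of 12 lower over the list alone), DNA methylation and chromatin (−0.14) and JA synthesis (−0.13). Camalexin and JA synthesis also depend on the pair. Camalexin scores were −0.474 and 0.86 in replicates 1 and 2, 4.42 and 3.99 in 3 and 4, and 3.31 in primed controls. JA synthesis scores were 4.322 and 3.954 against 5.091 and 5.266, with 4.82 in primed controls.

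Whether priming altered the difference between the pests was tested as a further interaction, which called OEP6 (−0.76 ± 0.12) and AT1G14890 (0.75), 2 genes of the 1827 with an unadjusted p under 0.05. DESeq2 called 45 and limma 4. OEP6 changed by −1.61 under mites and 0.55 under caterpillars in not-primed plants, and by −0.77 and 0.64 in primed plants. Its call ended without not-primed mite replicate 2 (adjusted p = 0.0666) or 4 (0.0862), primed mite replicate 2 (0.0509), not-primed caterpillar replicate 1 (0.0522), 2 (0.0767) or 4 (0.0999), or primed caterpillar replicate 1 (0.0601) or 2 (0.0605). That of AT1G14890 ended without the same libraries and also without not-primed mite replicate 3 (adjusted p = 0.0773) or primed mite replicate 1 (0.0565). ERF-branch genes had a lower interaction (0 of 12, 5 lower over the list alone; camera adjusted p = 3.94e-05), as had pattern genes (0.0133), and flavonoid genes a higher one (0.0482), each lost with an estimated correlation (adjusted p = 0.94). PDF1.2a, of that branch, was at 52.8 ± 27.5 CPM in not-primed and 99.1 ± 20.5 in primed plants under mites, and at 29.2 ± 31.2 and 6.89 ± 6.08 under caterpillars (SD, n = 4). Of the not-primed caterpillar libraries, replicate 4 was at 74.6 CPM and the other 3 at 8.68 to 24.7.

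The size of the response to each pest was compared between primed and not-primed plants, which share no library. Under mites 3769 genes rose and 3635 fell in both kinds of plant, against 1183 and 1171 by chance, and 28 went opposite ways, with r = 0.877 across genes. Under caterpillars 1814 rose and 1558 fell in both, against 344 and 322 by chance, and 4 went opposite ways, with r = 0.798. The slope of primed on not-primed responses was 0.87 for mites and 0.792 for caterpillars, and that of not-primed on primed responses 0.885 and 0.804. The orthogonal slope, which treats both alike, was 0.991 for each pest. The median absolute response, which was not tested, was lower in primed than in not-primed plants, at 0.273 against 0.323 for mites and 0.18 against 0.192 for caterpillars. Over genes called in either it was 0.385 against 0.477 and 0.322 against 0.353.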

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

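All tests in this part were chosen only after the results they test were seen, except the counts of other splits for the interactions of priming with caterpillars and with the difference between the pests, and a first test on the interaction with mites that proved void.

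Not-primed control replicates 3 and 4 had higher defence scores than replicates 1 and 2, with 4.44 and 4.75 against 2.28 and 1.73 for the MYC branch. RNA of mite-infested plants mixed into these libraries would bring every abundant mite-raised transcript in 1 share. Of 10 genes near silent in primed controls, the highest reached 3.82% of its infested level, with medians of 1.69% and 1.01% in replicates 3 and 4, below the medians of 7.87% and 9.17% of 14 MYC-branch genes. In replicates 1 and 2 the medians were 0.0549% and 0.0439% for the near-silent genes, and 1.93% and 0.786% for the MYC-branch genes. The near-silent genes thus were higher in replicates 3 and 4 too. The values argue against such a mixture as the whole source, but not against a smaller one as a part of it. RNA of caterpillar-fed plants was not tested. Primed controls labelled as not primed are argued against by a priming score from the genes called in both infested states, at most −1.156 in these libraries against at least −0.385 in primed ones (SD 0.126), while a batch, a harvest difference or unseen damage stay open, since the labels give no date or batch.

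The interaction of priming with mites called 221 genes in a test of the difference between the 2 kinds of plant, and either pair of the not-primed controls might be its whole source. A first test, written before its result, asked whether the called genes keep their sign and shrink by no more than a fold of 2 without either pair. It gave 221 of 221, but it ran on genes picked for the pattern and is void. What was put in its place is a count already known when its bounds were written, the lower of those without either pair. It was 111 genes, without replicates 1 and 2, and it cannot decide the question, since the controls kept may make calls of their own. How many genes would be left by either pair as the whole source was not measured. Of the 221 genes 63 were among these 111 and 204 were called without 3 and 4 (median absolute log2 fold change 0.499, against 0.448 and 0.556), so the pairs bear on which genes are called, and a biological interaction stays open as a hypothesis.

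Fitted on its own libraries that interaction called 187 genes, and 3 of 100 splits of the priming labels, the real one included, gave as many. The highest other split had 1390, several times the real count. It kept the real labels in the controls and exchanged most labels under mites, and so carries the priming effect itself, a structure of the samples. The interaction with caterpillars called 0 genes with edgeR on its own libraries, so that all 100 of 100 splits had to give as many and their number decides nothing. The highest other split gave 1076. That with the difference between the pests called 3, as many were reached in 7 of 100 splits, the highest other gave 438, and chance cannot be excluded.

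In the interaction with mites, the genes named by rule because the response differed between primed and not-primed plants were PYL5 (1.60), BT5 (1.57), AT1G06830 (1.5), AT5G61590 (1.24), AT5G21940 (1.21) and AT2G20670 (1.15) on the higher side. On the lower side were GolS2 (−1.84), P5CS1 (−1.40), BT1 (−1.32), AT4G21930 (−1.22), EGY3 (−1.08), HB-12 (−1.08), ABF3 (−0.76) and SOC1 (−0.55), of which GolS2, EGY3 and SOC1 lost their calls without several single libraries, among them primed mite replicate 4 (adjusted p = 0.0745, 0.0565 and 0.0825). Without not-primed control replicates 1 and 2 together, AT1G06830 (adjusted p = 0.0929), GolS2 (0.15) and SOC1 (0.0762) lost their calls. The interaction with the difference between the pests called 2 genes, OEP6 (−0.76) and AT1G14890 (0.75), and either call ended without not-primed caterpillar replicate 4 (adjusted p = 0.0999 and 0.141).

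Lists whose response differed by camera with the preset correlation had these medians. With mites they were sulfur (−0.52), abscisic acid (−0.59) and flower markers (−0.55). With caterpillars they were JA synthesis (−0.13), the ERF branch (−0.52), aliphatic glucosinolates (0.21), camalexin (−0.76), flavonoids (0.47), abscisic acid (−0.52), senescence (−0.43), DNA methylation and chromatin (−0.14) and guard cell, phloem and trichome markers (−0.17). For the difference between the pests they were the ERF branch (−0.54), pattern response (−0.36) and flavonoids (0.31). None of these calls held with an estimated correlation (adjusted p of at least 0.32). By list scores, several depend on which pair of not-primed controls is used. These are flavonoids, aliphatic glucosinolates, camalexin and JA synthesis with caterpillars, and sulfur with mites.

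A library stood apart from the other 3 of its group in 11 of 234 groups of values, where chance gives about 12. Primed control replicate 4 had a MYC-branch score of 4.26 (others 3.77 to 3.83) and an aliphatic glucosinolate score of 6.41 (others 6.06 to 6.11), and primed control replicate 1 a photosynthesis score of 12.21 (others 12.12 to 12.13). Among not-primed mite libraries, replicate 3 had an ERF-branch score of 3.41 (others 2.8 to 2.9), replicate 4 had VSP2 at 4510 CPM (others 3620 to 3710) and replicate 2 had CYP79F1 at 481 CPM (others 492 to 494). Primed mite replicate 3 had an ethylene score of 3.87 (others 3.55 to 3.6) and PDF1.2a at 130 CPM (others 87 to 91.7). Under caterpillars, not-primed replicate 1 had a flavonoid score of 5.0 (others 4.63 to 4.68), not-primed replicate 2 a cell division score of 2.66 (others 2.83 to 2.86) and primed replicate 2 a cell expansion score of 4.00 (others 3.69 to 3.73).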

How the results depend on the processing

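The fits without not-primed control libraries 1 and 2, or 3 and 4, and the check of the pairing of replicate numbers were chosen after seeing the data; the other alternatives were planned. With RLE size factors, and in the fits on only the libraries of the groups compared, the counts of changed genes stayed within 1.5 times their value. Of 421 called pairs of a named gene and a contrast, all kept their calls with RLE, and in the latter fits 418 kept and 2 lost them, with 1 not fitted. DESeq2 kept the call in 416 pairs, ended 1 and gave no adjusted p in the rest. Removing the filter on low counts ended 1, the replicate block ended 2, and limma on FPKM ended 5 with a pseudocount of 1, 7 with 0.1 and 16 without a filter. Over all fits without 1 library, 3408 pairs with a call kept it and 88 lost it. Without control libraries 1 and 2, 157 kept and 10 lost it, and without 3 and 4, 167 kept it. Of the pairs without a call, DESeq2 gained 7, the fits without 1 library 12, limma with a pseudocount of 0.1 gained 1, the unfiltered counts 1, the groups compared alone 10, and the fits without control libraries 1 and 2 or 3 and 4 gained 5 and 23, besides 5 that passed without 3 and 4 with the opposite sign. Depth limits the weakly expressed genes, and a fold as small as 1.5 was missed more often than 2 in simulated counts.

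Asking for an absolute log2 fold change of at least 1, which by construction keeps fewer genes, gave for mites and caterpillars against control 2071 and 904 genes in not-primed and 1926 and 931 in primed plants. It gave 227, 205 and 156 for priming in controls, under mites and under caterpillars, 712 and 866 for caterpillars against mites in not-primed and primed plants, 26 for the interaction of priming with mites and 0 for that with the pests' difference.

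The replicate number carried no pairing that could be seen. Of 60 pairs of libraries with the same number in different groups, the correlations of deviations lay between −0.17 and 0.20 with a median of 0.02, and 9 of 24 libraries matched best with one of their own number. With the replicate number as a block the counts for mites and caterpillars against control were 10268 and 5485 in not-primed and 9097 and 4715 in primed plants. The block gave 2868, 1267 and 1615 for priming in the 3 states, 5103 and 4364 for caterpillars against mites, 185, 0 and 4 for the interactions, 556 genes called for priming in all 3 states and 110 list calls.

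Without not-primed control libraries 1 and 2 the count for caterpillars was 2485, that for priming in controls 1370, and the interactions with mites and caterpillars gave 111 and 9 genes. Without libraries 3 and 4 the last 3 were 4537, 2069 and 486. In that fit VSP2 (1.71), LOX2 (1.28), MYC2 (0.63) and CYP79F1 (0.40) for priming in controls, and LOX2 (−1.41) for its interaction with mites, passed the threshold with a sign opposite to a value that had not passed. Without libraries 1 and 2, LOX2 (−0.88), MYC2 (−0.66), CYP79F1 (−0.42) and CYP79B2 (−0.74) passed as lower for priming in controls. PAD3 passed without 3 and 4 in each of the contrasts with these controls, at 4.54 for mites, 4.18 for caterpillars, 4.02 for priming, and −3.87 and −4.91 for the interactions. Which pair departs from the usual state of such plants was not tested.

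The interaction with mites had 691 genes by DESeq2 and 135 by limma without a filter. The interaction with caterpillars had 1 gene without a filter on counts, 10 by DESeq2 and 2 by limma without a filter. The interaction with the pests' difference had 45 genes by DESeq2, 4 by limma with either pseudocount and 5 without a filter. List calls fell to 24 with an estimated correlation. The cause of these differences was not tested.

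With single libraries left out, the counts lay between 9300 and 10187 for mites and 4175 and 5984 for caterpillars in not-primed plants, and between 8259 and 8619, and 3803 and 4786, in primed plants. Priming gave 1854 to 3302 in controls, 906 to 1176 under mites and 1032 to 1574 under caterpillars, with 467 to 553 genes in all 3 states. Caterpillars against mites gave 4053 to 4835 in not-primed and 3441 to 4039 in primed plants. The interactions gave 79 to 611, 0 to 2 and 0 to 5.

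The correlation of the pests' responses fell when the shared controls were split between them. With libraries 1 and 2, 1 and 3, 1 and 4, 3 and 4, or 2 and 4 serving the mites, r was 0.528, 0.715, 0.671, 0.729 and 0.717 in not-primed plants. The same splits gave 0.665, 0.691, 0.644, 0.641 and 0.637 in primed plants, and 2 and 3 gave 0.671. Each split fit has fewer controls. Over genes called in either response the correlation of primed and not-primed responses was 0.913 for mites and 0.894 for caterpillars.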

Other observations

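The tests in this part chosen only after the result was seen are those of clock genes and of the dark and low-sugar list, and the counts of other splits; the test on GC content and length was written before its result.

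Several gene groups were not called by camera under mites in not-primed plants. Ethylene synthesis and receptor genes were 5 higher and 3 lower of 11 (camera adjusted p = 0.584), cell division genes 1 higher and 1 lower of 13 (1 and 0 over the list alone; 0.995), and reference genes 0 higher and 2 lower of 8 (0.31). Clock genes were 3 higher and 5 lower of 14 (0.235), DNA methylation and chromatin genes 5 higher and 3 lower of 18 (0.761), camalexin genes 2 higher of 4 (0.235), flower markers 1 higher of 11 (0.235) and guard cell, phloem and trichome markers 3 higher and 2 lower of 12 (0.496). Flavonoid genes were 12 higher and 3 lower of 20 (0.0981), with a score of 4.23 against 3.15 in controls, without overlap (exact permutation p = 0.0286, the smallest possible, and 0.0429 adjusted over the lists). The same exact permutation p held for the scores of reference genes, lower by −0.12, and of guard cell, phloem and trichome markers, higher by 0.2, each without overlap. In primed plants under mites the camalexin score was higher by 0.96 without overlap (exact permutation p = 0.0286, adjusted 0.0386). The lists of ethylene, cell division, the clock and reference genes were called by camera in none of the 12 contrasts. Scores of reference genes were yet lower by −0.11, without overlap, under caterpillars in not-primed plants (exact permutation p = 0.0286, adjusted 0.0483). The same fall was seen in primed plants under mites (adjusted 0.0386) and caterpillars (0.0515). The ethylene score was higher by 0.36 without overlap in primed plants under mites (exact permutation p = 0.0286, adjusted 0.0386).

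A list of genes known to rise in darkness or at low sugar was written after 5 of its members (SEN1, TPS8, TPS11, bZIP1 and BT2) had been seen to be higher in primed plants. Of its other members, DIN10 was higher by 0.87, 1.55 and 0.73 in controls, under mites and under caterpillars, TPS9 by 1.33, 1.14 and 0.86, and the trehalose-phosphate synthase relative TPS10 (AT1G60140) by 0.88, 0.62 and 0.59. The asparagine synthetase gene ASN1 was at 1.35, 0.29 and 1.13, of which the value under mites did not pass (adjusted p = 0.69). BCE2 (0.381) and DIN4 (0.376) were called higher in controls but not under either pest, and BCAT-2 was called in no state.

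The 552 genes changed by priming in the same direction in all 3 infestation states could come from GC content or gene length bias, from another time of day or light at harvest, or from a dark or low-sugar type of expression. Once the trend on GC content and length was removed, 515 stayed past the threshold, and the trend held 0.489, 0.416 and 0.668% of the variance, which argues against that bias as the whole cause. Morning minus later clock genes (CCA1 and RVE8 minus TOC1, without LHY, PRR9 and PRR7, seen to move before) differed in primed libraries by −0.284 in controls and −0.297 under caterpillars, but the mite libraries overlapped (−0.442, exact p = 0.0571). An index with those 3 genes, tried first, gave −0.47, −0.529 and −0.433, without overlap in any state (exact permutation p = 0.0286 in each). Under mites CCA1 (−0.344, adjusted p = 0.000427), RVE8 (−0.246, 0.0129), LHY (−0.216, 0.0125) and PRR9 (−0.876, 1.71e-05) were called lower, and TOC1 and PRR7 were not called. CCA1 was not called in the other states. The clock list was not called for priming (camera adjusted p of 0.462, 0.411 and 0.731), but it mixes morning and later genes, so this cannot speak to a shift between them. Time of day and priming cannot be told apart, since primed and not-primed plants may have been harvested apart. The 7 other dark and low-sugar members, whose values had also been seen, scored higher in primed libraries by at least 0.572 (0.872, 0.616 and 0.572), without overlap in any state (exact permutation p = 0.0286 in each, the smallest possible, and 0.0322 adjusted over 9 tests), with 21 of 21 fold changes positive and 13 called, so primed plants may show a dark or low-sugar type of expression, which is a hypothesis from these same data, and a real effect of seed treatment was not told apart from conditions of growth or harvest.

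Other splits of the libraries, fitted on the groups compared alone, were counted for each comparison of 4 against 4. In each, 1 of 35 splits, the real one, gave as many genes, the smallest share that 35 splits can give. Mixed splits put the group difference into the spread, which keeps their counts low. A batch or harvest difference that follows the groups is not told apart from treatment by these counts. Mites against control called 9505 genes in not-primed plants (highest other split 0) and 9179 in primed plants (0), and caterpillars against control 4053 (1) and 4615 (0). Priming called 2080 genes in controls (0), 1570 under mites (1) and 1139 under caterpillars (60), and caterpillars against mites 5076 in not-primed (2) and 4077 in primed plants (0).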
